A study of Homo sapiens with 12 samples.

How the data were processed

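The series measured N4-acetylcytidine (ac4C), an acetylated form of cytidine in RNA, by ac4C-RIP-seq in HK-2 cells, an established line of human renal tubular epithelial cells. In this assay RNA is broken into fragments, fragments bound by an antibody against ac4C are pulled down (IP), and the pulled-down and the starting RNA (input) are sequenced. The 12 samples form 3 wild-type (WT) and 3 NAT10 knockout (KO) pairs of an IP and an input library. NAT10 is the acetyltransferase that deposits ac4C. The sample labels call the second genotype a knockout, whereas the series text calls it a knockdown, and KO is used here for the group as the sample labels name it. The labels do not say that replicates came from separate cultures. Each p-value that compares lists therefore measures only the spread between these samples, which may be technical. The p-values of gene groups and annotation terms take genes as units and measure no spread between samples. The labels give no batch, so genotype and any batch of preparation cannot be told apart.

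The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4 and the build hg38, with no role or order stated. Per the file headers and the peak names, the authors called sites with MACS (version not given in the sources used here), 1 list per pair of IP and input, with no pooling of replicates. How the sites were limited to messenger RNA and annotated is not given in the sources used here. Each deposited row holds a site's coordinates, a score, its length, its gene, the significance, the fold enrichment, a false discovery rate and the part of the transcript it lies in. The score, per the file headers and its equality with the significance column, is MACS's negative log10 of the p-value times 10; it was at least 50 in every list. The fold enrichment of IP over input is the authors' own ratio per site and was at least 2 in every list. The false discovery rate is the authors' percent value per site. Score, fold and false discovery rate were used only to describe, rank or filter sites within a list, not to test 1 list against another. The exception is a gene's printed coordinates and transcript part, which are those of its highest fold over the lists. A list holds no read counts and no library totals, so the sequencing depth behind a site is unknown and no interval on a site could be given. Over the 6 lists, 17 rows are empty in the copies used here and were not analysed here.

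The rows of each list were checked for internal agreement. In KO replicate 1, the score beside the coordinates equalled the significance beside the gene, and the lengths matched, in only 1 of 13818 rows, and 4.43% of the rows with a recognised gene lay on that gene's chromosome. The coordinate columns and the gene columns of this list therefore stand in different row orders. The list was rejoined on equal significance and equal length, with rows of equal keys settled by the gene's chromosome. This paired 13344 rows, of which 99.9% then lay on the gene's chromosome, and left 474 rows unpaired. The join was tested on simulated data by shuffling the gene columns of the WT lists: 99.1% to 99.3% of rows were joined, and 100% of the joined rows had the right gene. Analyses of regions used the coordinate columns and the transcript part beside them, and analyses of genes used the gene columns, so only the naming of regions and the filter on fold needed the join. In the other 5 lists all rows matched as they stand.

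The coordinates are given as in the files. In the 5 lists in original order, 12.9% to 13.5% of sites lay within the GRCh38 span of the gene beside them although over 99.8% lay on its chromosome, so the files' coordinates are not those of GRCh38, and the build they use is not given in the sources used here. Site length equals end minus start in the files, so starts were read as counted from 0 and are printed 1 higher. Gene symbols were updated through the GeneID, or otherwise the transcript, with the RefSeq table for GRCh38.p14, which was used for names and chromosomes only. Between 113 and 172 sites per list had no match and kept the files' name.

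Sites of the 6 lists were merged into regions wherever they overlapped by at least 1 base, and strand was not used here. The overlap of 2 lists is the Jaccard index, the regions with a site in both divided by the regions with a site in either. Values per list were compared between genotypes by a two-sided exact permutation test of the difference of means, whose smallest possible p with 3 lists against 3 is 0.1. No comparison of lists here can therefore pass a threshold of 0.05, and differences are given as values. The mean Jaccard index within genotypes minus that between genotypes was set against all 10 splits of the 6 lists into 3 and 3. A region or gene found in all 3 lists of 1 genotype and none of the other has a Fisher's exact p of 0.1 by itself, so such regions and genes were counted, not tested one by one. Because several statistics per list were compared, their p-values are printed unadjusted.

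Before the data were examined, 20 gene lists were fixed, covering extracellular matrix, TGF-beta signalling, epithelial and mesenchymal markers, inflammation, cell death, translation, ribosomes, metabolism, stress, cell cycle, p53, lysosome, proximal tubule and other kidney cells. For each, the mean over members of KO lists with a site minus WT lists with a site was compared with 10000 random gene sets of the same size, matched on the number of lists with a site (a two-sided permutation of gene labels, Benjamini-Hochberg over the 20 lists). Genes are not replicates, so this test describes these 6 lists. On simulated data in which 40% of the members of a list of 15 genes were placed in all WT and no KO list, 95% of the simulations passed the adjusted threshold, and 0% passed with 20% of the members so placed. These simulations used a background with the list names shuffled within each gene, where 1.49% of genes fell in all WT and no KO list. In the real lists 1213 of 10252 genes did, so the simulated shares need not hold for the real lists. Genes named in the text follow a rule set before the data were examined: NAT10 and its partner THUMPD1; 20 genes of fibrosis and inflammation; the 15 WT-only and 10 KO-only genes whose best site had the highest mean percentile of fold within the lists of that genotype; and up to 4 members of each gene list with the largest difference in number of lists, ties by alphabet. Genes named outside this rule were chosen after their values were seen, and this is said where they occur.

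After the data had been seen, the KEGG and Gene Ontology terms that the lists give for each gene were tested among WT-only and KO-only genes. Fisher's exact test was used against all annotated genes with a site, for terms with at least 15 such genes, with Benjamini-Hochberg adjustment within each annotation and genotype. A list of 38 keratinocyte genes was also chosen then.

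The alternatives were a fold of at least 4, the best 13818 sites of every list (the length of the shortest), leaving out each replicate, a replicate block, an overlap of at least 50% of the shorter site, at least 2 lists against none, merged regions as the unit of the transcript part, random sets without matching and Fisher's exact test for the gene lists. That Fisher's exact test counted members with a site in at least 2 WT lists and no KO list, so it covered the WT side only. The planned share of sites with a repeat of evenly spaced cytidines was not run, because no sequences were used here, and the planned test of read counts per site was not run, because the lists give no counts. Calculations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1.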

Results

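ac4C sites were mapped in HK-2 cells, a human proximal tubule cell line widely used in work on kidney injury, in WT cells and in cells labelled as NAT10 knockout. The series title places the comparison in renal fibrosis: it asks which transcripts carry NAT10-dependent ac4C. Each of the 3 WT and 3 KO pairs of IP and input gave 1 list of sites. The WT lists held 17541, 17107 and 15289 sites in 7235, 7188 and 6737 genes, and the KO lists 13818, 17872 and 19136 sites in 6698, 7658 and 7894 genes. The authors' false discovery rate was high throughout: no site in any list was under 5%, and sites over 50% made up 92.8%, 92.1% and 91.9% of WT lists 1, 2 and 3 and 62.4%, 68.1% and 43.2% of KO lists 1, 2 and 3. The fold enrichments quoted here are the authors' values for single sites and describe sites within their own list. Folds given for several lists are the gene's highest in each list. Coordinates and transcript part are those of the highest over the lists, and whether all lists share that site was not checked.

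The targeted gene was examined first. The NAT10 transcript (GeneID 55226) held 11, 11 and 8 sites in the WT lists and 2, 5 and 9 in the KO lists, a mean of 10 ± 1.73 against 5.33 ± 3.51 sites (SD, n = 3 each; exact permutation p = 0.2), a difference of -4.67 that was -3 without KO replicate 1. Its site of highest fold lay in the coding sequence on chromosome 11, from 34152928 to 34153078 in the coordinates of the files. THUMPD1, the adaptor that works with NAT10 on transfer RNA, held 1 site in every WT list and none in any KO list. That site spanned the stop codon, on chromosome 16 from 20747751 to 20748041, with a fold of 10.2, 14.3 and 12.2 in WT replicates 1, 2 and 3. NAT10 thus carried called sites in all 6 lists, and a site list gives no transcript level, so the lists do not show loss of the NAT10 transcript.

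Among the genes of fibrosis fixed beforehand, several had site numbers that did not overlap between genotypes. COL4A1, a chain of basement membrane collagen, held 3.67 ± 0.577 sites in WT and 12.3 ± 2.52 in KO lists. TGFB1, the central profibrotic cytokine, held 4 sites in each WT list and 1, 2 and 2 in the KO lists. SMAD7, an inhibitor of TGF-beta signalling, had no WT site and 2 sites in each KO list, with highest folds of 607, 551 and 438. The highest, in KO replicate 1, lay over the stop codon on chromosome 18 from 46447275 to 46447886. SMAD3, a transducer of TGF-beta signalling, had 2.33 ± 1.15 against 4.33 ± 0.577 sites. For each of these 4 genes and for THUMPD1 the 3 lists of 1 genotype did not overlap those of the other (exact permutation p = 0.1, the smallest that 3 against 3 lists allow, which chance gives to 10% of single comparisons). Of all 10252 genes with a site, 1213 had one in all WT and no KO list and 1534 in all KO and no WT list. Lists without overlap were thus common among all genes and do not set these genes apart. Among sites with a fold of at least 4, a setting applied to single genes after the data had been seen, the difference of KO minus WT was -1.33 in place of -2.33 sites for TGFB1 and 1 in place of 2 for SMAD7.

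The remaining fixed genes overlapped between genotypes. COL1A1 held 1.33 ± 0.577 sites in WT and 2.67 ± 1.15 in KO lists (exact permutation p = 0.3), and FN1, which encodes fibronectin, 6 ± 0 and 7.33 ± 1.53 (exact permutation p = 0.4). The difference for COL1A1 was 0.667 sites without KO replicate 3, and that for FN1 was 0.5 without it and turned to -2.67 among sites with a fold of at least 4. The intermediate filament gene VIM, the cytokine genes IL6 and CXCL1 and the pyroptosis effector GSDMD held 1 site in every list. CDH2 held 4 or 5 sites in every list, with a difference of 0 that was -1.33 with a fold of at least 4 and -0.667 with equal list lengths. NLRP3 held 2, 3 and 2 sites in WT and 3, 1 and 0 in KO lists, TGFBR1 held 1, 2 and 0 in WT and none in KO lists (none in either with a fold of at least 4), and TGFB2 between 1 and 3 in every list, with a difference of -0.333 sites that turned to 1 among sites with a fold of at least 4. SNAI2 had 1 site in WT replicate 2 and 1 in KO replicate 2. No site was listed for CCN2, CDH1, CCL2 or CXCL8 in any list.

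**Figure D1:**
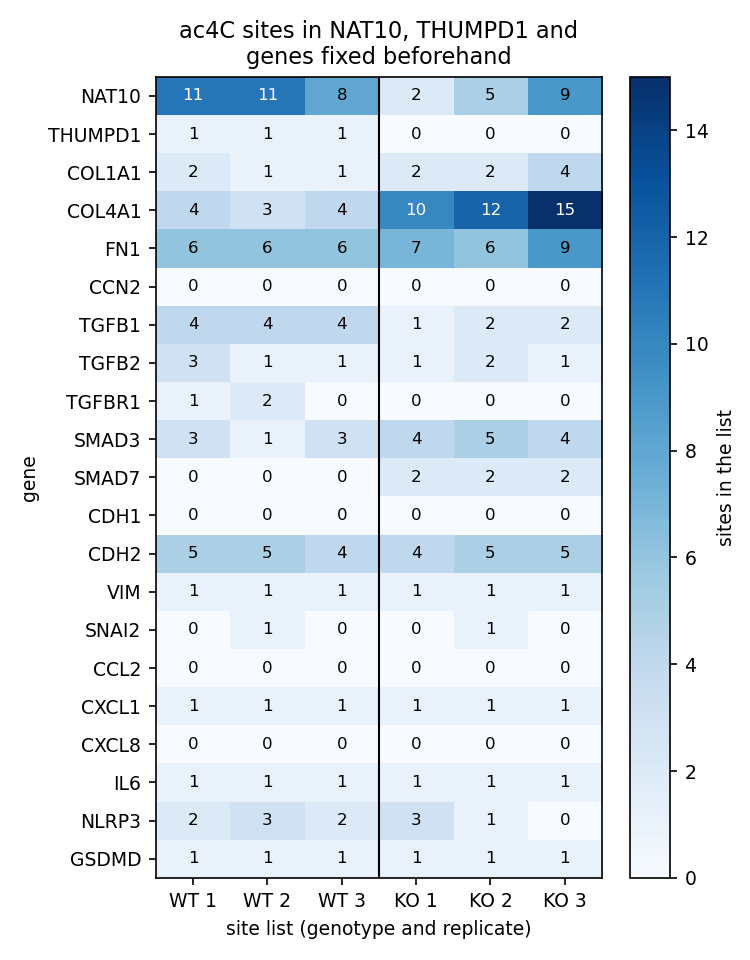
Number of ac4C sites (colour and digits) in each of the 6 lists, WT to the left and KO to the right of the line, for NAT10, THUMPD1 and 19 of the genes fixed beforehand. COL4A1 held 3 or 4 sites in WT and 10, 12 and 15 in KO lists, whereas TGFB1 held 4 in each WT list and 1 or 2 in KO lists.

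The lists of both genotypes were next compared in size. KO lists did not hold fewer sites than WT lists: the mean was 16646 ± 1195 in WT and 16942 ± 2778 in KO (SD, n = 3 each; exact permutation p = 0.8), and the direction turned when any 1 of WT replicate 3, KO replicate 2 or KO replicate 3 was left out, over a range of differences from -801 to 1858 sites. The number of genes with a site was 7053 ± 275 in WT and 7417 ± 633 in KO (exact permutation p = 0.5). Sites per gene averaged 2.36 ± 0.0798 in WT and 2.27 ± 0.188 in KO lists (exact permutation p = 0.6). The median site was 164 ± 3.21 bases long in WT and 174 ± 3.79 in KO lists, with no overlap between genotypes (exact permutation p = 0.1).

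The positions of sites, in contrast to their number, separated the genotypes. The 6 lists merged into 35919 regions, of which 7819 held a site in all WT and no KO list, 7501 in all KO and no WT list, and 2899 in all 6. Of the 12596 regions found in all WT lists, 62.1% had no KO site, and of the 11503 found in all KO lists, 65.2% had no WT site. The Jaccard index averaged 0.686 for pairs of lists of the same genotype (0.595 to 0.757) and 0.161 for pairs of different genotype (0.148 to 0.175). The difference of 0.525 was the largest of the 10 splits of the lists (exact permutation p = 0.1, the smallest possible), and it lay between 0.5 and 0.553 when 1 replicate was left out. Most regions of 1 genotype lay in genes that had a site elsewhere in the other: 79.2% of WT-only and 72.5% of KO-only regions. Sites with identical start and end numbered 8669 to 11089 per pair of lists within a genotype and 1135 to 1580 between genotypes. The labels do not say that replicates came from separate cultures, so the closeness of replicates may be technical.

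**Figure D2:**
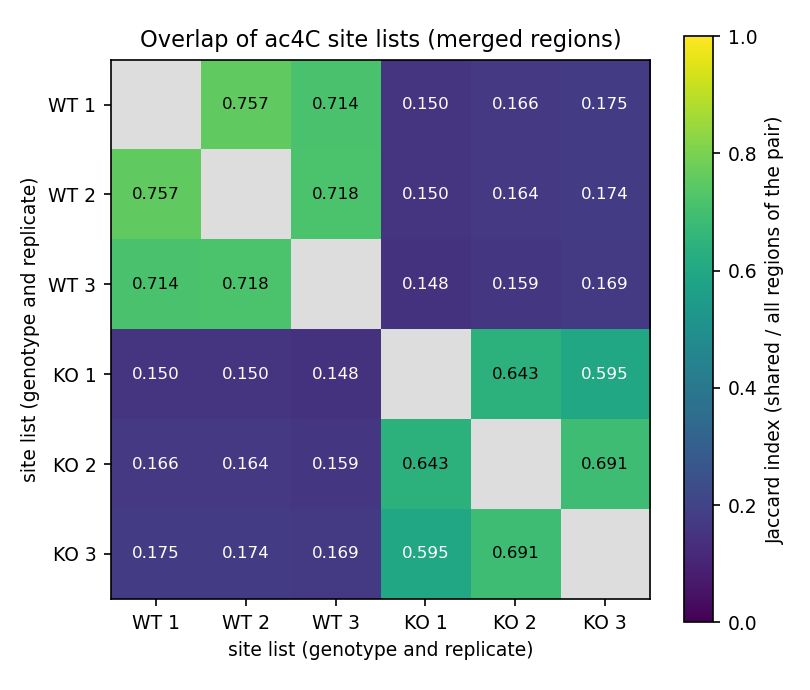
Jaccard index (colour and digits, from 0 to 1) of the merged site regions of each pair of lists, WT and KO replicates 1 to 3 on both axes, with the diagonal left grey. Pairs within WT lie between 0.714 and 0.757, pairs within KO between 0.595 and 0.691, and the 9 pairs of WT with KO between 0.148 and 0.175.

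At the level of genes the genotypes shared more. Of 10252 genes with a site in any list, 3991 had one in all 6, 1213 in all WT and no KO list, and 1534 in all KO and no WT list. The gene-level Jaccard index averaged 0.839 within and 0.527 between genotypes. Of the genes found in all lists of 1 genotype, 19.3% (WT) and 24.7% (KO) had no site in the other.

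The WT-only genes with the highest fold within their lists included COL4A5, a chain of basement membrane collagen mutated in Alport syndrome. It had 4 sites in every WT list and highest folds of 2475, 1669 and 2198. The highest, in WT replicate 1, was at a coding site on chromosome X from 107938497 to 107938669. BCL2L11, the proapoptotic BH3 protein BIM, held 2 sites per WT list, with highest folds of 1914, 2797 and 2000. The highest, in WT replicate 2, lay over the start codon on chromosome 2 from 111881376 to 111881713. MBTPS2, the site-2 protease that releases membrane-bound transcription factors, held 2 sites per WT list, with highest folds of 3543, 3408 and 3696. The highest, in WT replicate 3, was only 5 bases long. CYRIB, CYTL1 and INTS9, which encodes a subunit of the Integrator complex, had highest folds of 3081, 2875 and 2609. The other 9 were IER5L, RPGR, PARM1, GPHN, GSTM4, SSBP2, MYO5A, DNAH8 and RNF121, of which RNF121 held 5, 5 and 4 sites and MYO5A 3 per list, while the best sites of DNAH8 and RNF121 were 10 and 38 bases long.

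The KO-only genes of highest fold were led by ZNF280A, with 1 site per KO list in the 5' UTR on chromosome 22 from 22874464 to 22874613 and folds of 4273, 4385 and 4394. CER1, a secreted inhibitor of Nodal and BMP signalling, and TRPC7, a cation channel, each held 1 site per KO list with folds between 2032 and 2146. NFIB, a transcription factor of the nuclear factor I family, held 5, 5 and 6 sites, and ABCA12, a lipid transporter of the epidermis, 4 per list. FOXO1 held 1 coding site per KO list on chromosome 13 from 41239726 to 41239969 (folds 1088, 1030 and 1006), NFATC1 held 2 and DHODH, the mitochondrial enzyme of pyrimidine synthesis, 3. FAM118B and SELENOO completed the 10 genes. A site in all lists of 1 genotype and none of the other has an exact p of 0.1 for any single gene, so none of these genes passed a test alone.

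The part of the transcript that carried sites was nearly the same in both genotypes. Sites in the coding sequence (CDS) made up 56.6% ± 0.569 of WT and 56.2% ± 0.406 of KO lists (SD, n = 3 each; exact permutation p = 0.4). The 5' UTR took 6.10% ± 0.0967 in WT and 7.09% ± 0.166 in KO, the start codon 13.7% ± 0.182 and 14.6% ± 0.347, and the 3' UTR 9.97% ± 0.354 and 8.76% ± 0.122. In these 3 parts the lists of the genotypes did not overlap (exact permutation p = 0.1 each, the smallest possible, among 5 parts compared). The stop codon took 13.7% ± 0.144 in WT and 13.4% ± 0.372 in KO (exact permutation p = 0.3). Regions shared by all 6 lists lay at the start codon in 21.5% and in the 3' UTR in 4.93% of cases, against 10.8% and 12.2% of WT-only and 12.8% and 10.3% of KO-only regions.

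**Figure D3:**
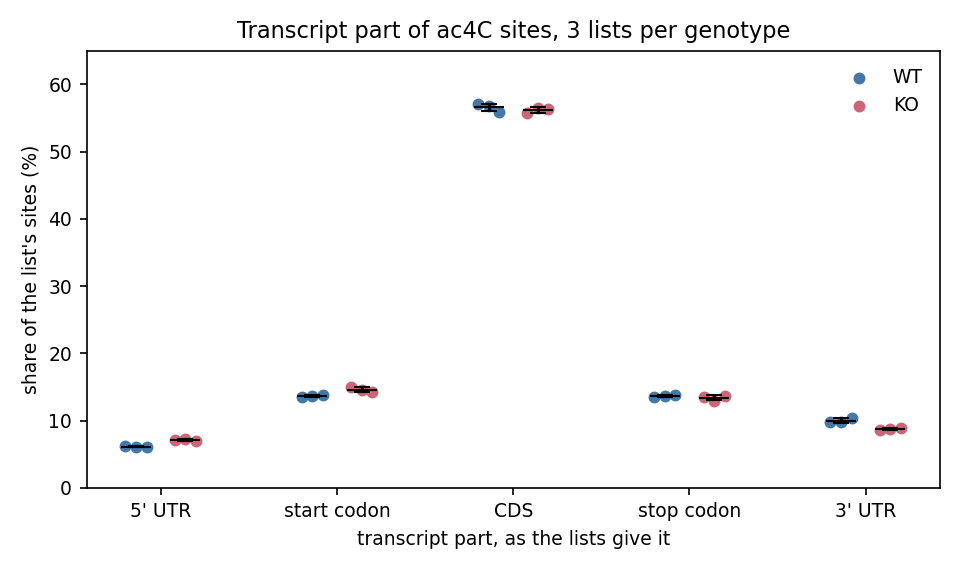
Share of each list's sites (vertical axis, %) in 5 parts of the transcript, with 1 point per list and the mean ± SD of the 3 lists of each genotype in black. The CDS held 56.6% of WT and 56.2% of KO sites, and the 3' UTR 9.97% and 8.76%.

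Whether sites moved into or out of groups of genes was asked with the 20 gene lists. Genes of the p53 response and senescence had the largest shift towards WT: 14 ± 1 members had a site per WT list and 8 ± 1.73 per KO list. CDKN1B, MYC and FOS, a cell cycle inhibitor and a pair of immediate early transcription factors, had a site in all WT and no KO list, and GADD45B in 2 WT lists and no KO list. The mean difference was -1.20 lists over the 15 members with a site (permutation p = 0.0081, random gene sets), and 9 members had fewer KO than WT lists, 1 more and 5 equally many. Adjusted over the 20 lists, the permutation p was 0.16, so neither this nor any other gene list passed 0.05. At the unadjusted 0.05, 1 list passed. Fisher's exact test of members with a site in at least 2 WT lists and no KO list gave 0 after adjustment. Members on the KO side were not tested in that way. The p53 list alone passed when WT replicate 1 (adjusted permutation p = 0.014) or WT replicate 2 (adjusted permutation p = 0.016) was left out, in a range of 0.014 to 1 over its alternatives.

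Glycolysis and pyroptosis genes lay on the KO side without passing the test. Of the glycolysis genes, 14.3 ± 0.577 had a site per WT list and 19 ± 0 per KO list, with the glucose transporter gene SLC2A3 and the enzyme genes PGK1, LDHB and PDK1 in all KO and no WT list (mean difference 0.667 lists, adjusted permutation p = 0.68). Of the pyroptosis genes, 5 ± 1 had a site per WT and 8 ± 0 per KO list. CASP4, the inflammatory caspase that senses lipopolysaccharide, and the channel gene PANX1 were KO-only, CASP8 had sites in 1 WT and 3 KO lists, and GSDME in 1 KO list (mean difference 1 list, adjusted permutation p = 0.68).

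Fibrosis gene groups contained members in both directions. In the extracellular matrix list, COL3A1, COL4A5, COL5A1 and FBLN1 were among 6 WT-only genes, with 4, 7 and 6 sites for COL3A1 in WT replicates 1, 2 and 3, whereas 4 genes were KO-only and 24 had sites in all 6 lists (mean difference -0.0455 lists, adjusted permutation p = 1). In the TGF-beta list 5 genes were KO-only, among them the receptor genes ACVR1 (5 sites per KO list) and ACVR1B, SMAD1 and the SMAD inhibitor gene SKIL, and 1 was WT-only (mean difference 0.321, adjusted permutation p = 1; 0.769 with a fold of at least 4, adjusted permutation p = 0.37). In the epithelial and mesenchymal list, ACTA2 and CNN1, which encode smooth muscle actin and calponin of myofibroblasts, and the integrin genes ITGB1 and ITGB6 were the 4 WT-only genes, against 2 KO-only genes, with 25.3 ± 1.53 members per WT and 21.7 ± 1.53 per KO list (mean difference -0.379, adjusted permutation p = 0.68). Of the inflammation genes, the chemokine gene CCL20 was WT-only and TNF, CHUK and VCAM1 were KO-only (mean difference 0.148, adjusted permutation p = 1).

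In the lists on translation, ribosomal protein genes had 14.7 ± 1.15 members with a site per WT and 20 ± 2 per KO list, with RPL14, RPL17 and RPL26 among 8 KO-only genes, against 3 WT-only genes (mean difference 0.571, adjusted permutation p = 1). Translation factors had 24.3 ± 0.577 and 22 ± 1, with ABCE1, EIF2S1 and EIF3G among 4 WT-only and EIF4A1 among 4 KO-only genes (mean difference -0.233, adjusted permutation p = 1). Aminoacyl-tRNA synthetase genes had sites almost throughout, 16 of 20 in all 6 lists, with HARS1 KO-only (mean difference 0.05, adjusted permutation p = 1). FARSB and WARS1 had sites in 3 WT and 2 KO lists, and AARS1 in all. Of the ribosome biogenesis and RNA modification genes, the pseudouridine synthase genes DKC1 and PUS7 and the m6A writer subunit gene METTL14 were among 5 WT-only genes and GNL3 among 3 KO-only (mean difference -0.0513, adjusted permutation p = 1).

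The other lists held WT-only and KO-only members in differing numbers, with no list past the test (adjusted permutation p = 1 for each). Among ferroptosis and antioxidant genes, GPX4 and AIFM2 were WT-only and TXN and TXNRD1 KO-only, with a mean difference of 0.1. Among genes of the unfolded protein response, ATF4 was among 3 WT-only and CALR, CRELD2 and DNAJB9 among 4 KO-only (0.231), and among chaperone genes HSPA8 and HSPB1 were WT-only and HSPA1B and DNAJA1 KO-only (0). Oxidative phosphorylation had ATP5ME, COX5B and CYCS among 5 WT-only and NDUFB9 among 2 KO-only genes (-0.111, and -0.0370 without WT replicate 3, -0.0192 without KO replicate 1 and -0.260 without KO replicate 3). The cell cycle list had BUB1 and BUB3 among 4 WT-only and CCNB1 and CDC25A among 3 KO-only genes (-0.0909). The lysosome list had ATG9A, ATP6V1H and GLA as its 3 WT-only genes and GAA among 4 KO-only genes (0.0417), and the histone list had H2AZ2 on the WT side, with H1-10 in 3 WT and 2 KO lists and H4C8 in 2 KO lists (0.167). Of the proximal tubule genes, 16 had a site: the cadherin gene CDH16 was among 5 WT-only genes, and CDH6, DPP4 and HAVCR1, the kidney injury marker KIM-1, were the 3 KO-only genes, with 9.67 ± 0.577 and 8.67 ± 0.577 members per list (-0.188). Of 32 markers of other kidney and blood cells, 5 had any site, MCAM was KO-only, ATP6V1B1 had a site in 1 WT list, and LYZ and PDGFRB had sites in all 6 lists (0.4).

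**Figure D4:**
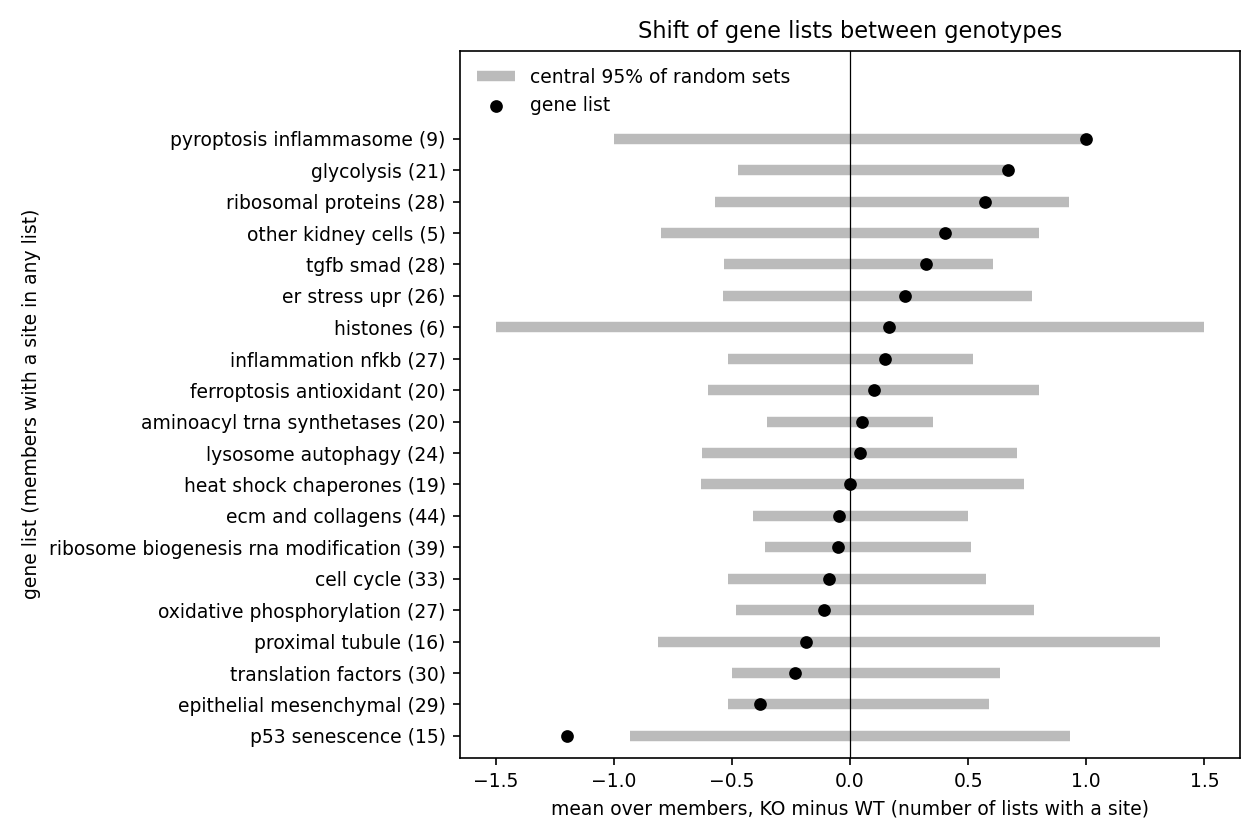
Mean over the members of each gene list of KO lists with a site minus WT lists with a site (points, horizontal axis in lists), beside the central 95% of 10000 matched random sets (grey bars). The p53 and senescence list, at -1.20, lies outside its bar.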

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

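NAT10 and the single named genes were put through these settings only after the data had been seen; the other settings were fixed before the data were examined. The 4 counts of regions and genes found in 1 genotype stayed within 1.5 times of their reported values under every setting run, from 6186 to 11232 regions and from 1213 to 2016 genes. The Jaccard difference stayed between 0.5 and 0.553, and the CDS share of KO minus WT between -1.09 and -0.178 percentage points. The difference in genes with a site per list stayed positive, from 125 to 723. The NAT10 difference stayed between -6.5 and -3 sites. With 3 lists against 3 no p could fall under 0.1, so these p-values say nothing of stability.

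The difference in sites per list ran from -801 to 1858 when 1 replicate was left out, and the cause was not tested. The number of gene lists past the threshold ran from 0 to 1 when 1 replicate was left out, the p53 list in each case, and was 0 in all other settings. None of the gene lists whose mean difference turned sign passed the threshold in any setting, and the cause was not tested. With a fold of at least 4, the mean difference was -0.0526 lists for aminoacyl-tRNA synthetases, 0.0286 for ribosome biogenesis, 0.0968 for the cell cycle and -0.0435 for the lysosome. With equal list lengths it was -0.0370 for inflammation, -0.167 for histones, 0.182 for the cell cycle and -0.0455 for the lysosome. Leaving out 1 replicate gave ranges of -0.102 to 0.0341 for extracellular matrix, -0.194 to 0.0513 for ribosome biogenesis, -0.0263 to 0.2 for ferroptosis and -0.109 to 0.208 for the lysosome. It also moved by over 1.5 times oxidative phosphorylation (-0.260 to -0.0192), the cell cycle (-0.152 to -0.0303), inflammation (0 to 0.222), histones (0 to 0.25), aminoacyl-tRNA synthetases (0.025 to 0.1) and other kidney cells (0.3 to 0.75), and chaperones from 0 to between -0.0526 and 0.0526. With a fold of at least 4, values over 1.5 times from those reported and of the same sign, or from or to 0, were 0.769 for TGF-beta, -0.444 for translation factors, 0.333 for chaperones, -0.3 for oxidative phosphorylation, 0.368 for ferroptosis, -0.114 for extracellular matrix, 0.0370 for inflammation and 0 for proximal tubule and other kidney cells. With equal list lengths they were -0.143 for translation factors and for epithelial and mesenchymal genes, 0.105 for chaperones, -0.292 for oxidative phosphorylation, 0.35 for ferroptosis, -0.194 for ribosome biogenesis and 0 for extracellular matrix and other kidney cells. Of 368 values of single named genes, 18 moved by more than the SD of the lists.

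Replicate numbers are shared between genotypes, but same-numbered lists did not deviate together, with correlations of -0.00718, 0.0170 and -0.00549 over genes for numbers 1, 2 and 3. A replicate block leaves each difference and count as it was by construction, so it says nothing of their stability, and only the p-values could change. The differences were 296 sites per list (exact p = 0.75), 363 genes (0.75), -0.416 percentage points of CDS (0.75) and 0.525 in the Jaccard index (0.25, the smallest that 3 pairs allow). The repeat of cytidines (all its settings) and the read-count tests were not run. The depth behind each list is unknown, so an absent site is not a measured absence of ac4C.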

Other observations

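Of the tests reported here, that of sites near the calling threshold and that of near-identical genes were set before their result was seen, and the others, or their final bounds, after. Genes in this part were chosen after their values were seen. The annotation terms in the lists were tested for enrichment among WT-only and KO-only genes against all annotated genes with a site, by Fisher's exact test within 8 families, KEGG and 3 branches of Gene Ontology for each genotype. KEGG gave 0 terms past an adjusted p of 0.05 in either genotype, with 15 (WT) and 8 (KO) of 204 at the unadjusted 0.05. Cellular components gave 3 and 3 of 267, molecular functions 3 and 1 of 304, and biological processes 0 and 2 of 672. Genes of the nucleoplasm were underrepresented among WT-only genes (164 of 1992, 8.23%, against 11.6% of all, adjusted exact p = 1.9e-05). Among KO-only genes they went the same way without passing (242 of 1992, 12.1%, against 14.4% of all, adjusted exact p = 0.079). Chromatin binding genes were underrepresented among WT-only genes (13 of 277, adjusted exact p = 0.011). Poly(A) RNA binding genes were underrepresented in both genotypes (69 and 90 of 901, adjusted exact p = 0.011 and 0.037). Genes of integral membrane proteins were overrepresented in both (285 and 336 of 1978, adjusted exact p = 0.0015 and 0.023). The real split of the 6 lists put 12 terms past the threshold and the highest other 0, so 1 of 10 splits gave as many, but the other splits held only 7 to 22 genes to test, which leaves this contrast uninformative, and 10 splits are too few for a share under 0.05.

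The most specific terms belonged to the epidermis, on the KO side. KO-only genes made up 9 of 15 cornified envelope genes (odds ratio 8.98, adjusted exact p = 0.0076), 10 of 18 keratinocyte differentiation genes (7.57, adjusted exact p = 0.033) and 9 of 16 keratinization genes (7.78, adjusted exact p = 0.035). They included LORICRIN, HRNR, SPRR2D, LCE1A, LCE1C, LCE1F, LCE2B and LCE5A, neighbours in the epidermal differentiation complex of chromosome 1, and KRT10, DSP and ABCA12 elsewhere. LCE2B had folds of 174, 131 and 106 within the KO lists, and LORICRIN 34.7, 25.6 and 21.9. HRNR, with 3.63, 3.21 and 2.79, and KRT10, with 3.18, 3.37 and 3.3, lay near the lowest listed fold of 2. Of the 26 genes with any of these terms, 12 were KO-only and 2, ADAM9 and CLIC4, were WT-only. Sites in FLG, the filaggrin gene of the same complex, were present in all 6 lists.

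The following explanations of the epidermal terms were set against the data. Genomic DNA in the KO libraries stays open: of 390 olfactory receptor genes, silent in cultured epithelial cells, only 3 had any site, 0 KO-only and 1 WT-only (ratio 0), and DNA in both IP and input need not give a site. The LCE genes are near-identical copies that may share reads: counted as 1 gene they left odds ratios of 5.99, 5.19 and 6.05 and a highest Fisher p of 0.0081, under the bound of 0.05 set beforehand, yet no adjusted p under 0.34, so that bound was laxer than the threshold that named the terms and shared reads stay open. RNA of keratinocytes in the KO libraries also stays open: of 38 keratinocyte genes, 10 had any site and 6 of these (60%) were KO-only (KRT10, KLK5, FLG2, SBSN, CALML5 and KPRP), too few genes for a bound that was rewritten once the values had been seen, and KRT5 was WT-only, KRT1 and KRT2 had no site, and a site list does not give RNA levels. A change of the cells themselves after loss of NAT10 is the biological explanation the design offers, as an untested hypothesis.

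The small overlap between genotypes, given the close overlap within them, is the pattern most in need of a second look. Sites that just missed the threshold in the other genotype would be weak ones. Of the tenth of all-WT regions with the highest fold, 56.95% had no KO site. Of the tenth of all-KO regions with the highest fold, 72.2% had no WT site. Regions without a counterpart were thus not limited to those of low fold, although in WT the share was higher in the tenth with the lowest fold (75%). Regions were ranked by fold, whereas every listed site also had a score of at least 50. A high fold need not mean a score far from that floor, so the threshold stays open as an explanation. Transcripts too low in the other genotype stay open too. At least 72.5% of the regions of 1 genotype lay in genes with a site in the other. However, of the 10252 genes with any site, KO replicate 3 alone had a site in 7894 and WT replicate 1 alone in 7235. A high share was thus likely whatever the cause, and a site list gives no transcript level. An exchange of IP and input in 1 genotype could not be told apart from a true shift of sites. Sites in the 3' UTR overlapped sites of the other genotype 1.26 to 1.35 times as often as the same sites did on average when moved by 300 to 1000 bases. These ratios lay between the bounds of 1 and 1.5 set for this test, and pairs within a genotype gave 3.36 to 3.61. Against the move with the highest overlap, the ratios were 1.08 to 1.15 between genotypes and 2.19 to 2.45 within a genotype. A difference in preparation batch cannot be told apart from genotype, since the labels give none, and loss of NAT10 itself remains a hypothesis.

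The split of the lists by genotype gave 15320 regions and 2747 genes found in all lists of 1 side and none of the other, while the highest of the other splits gave 92 regions and 22 genes. In both cases 1 of the 10 splits gave as many, and for the gene lists, where the real and the highest other count were 0, all 10 did; with 10 splits the share cannot fall under 0.05.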
